A study of rat gut metagenome with 11 samples.

How the data were processed

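Bacterial DNA from the lumen of the terminal ileum of 11 male F344 rats was profiled by sequencing part of the 16S rRNA gene, a ribosomal gene carried by all bacteria. Per the labels' protocols, rats aged 24 weeks received chow containing lansoprazole, a proton pump inhibitor that blocks gastric acid secretion, at a stated 5 mg/kg, or plain chow. Feeding lasted 50 weeks. After a 12 h fast, saline was passed through 1 cm of ileum from each rat and the bacteria were pelleted for DNA extraction. The V1 to V3 regions were amplified with barcoded primers 9F and 541R over 30 PCR cycles and sequenced by pyrosequencing on a GS FLX instrument.

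Each sample was placed in its group by its own treatment label, which gave 6 lansoprazole and 5 control samples. The study's design text states the opposite numbers, 5 with and 6 without the drug. The sample labels were used throughout, and the conflict was not resolved. Titles of lansoprazole samples began with B (3 samples) or H (3 samples) and those of controls with C. The meaning of these letters was not given in the sources used here, so they were treated as a possible cage or batch that overlaps with treatment. Replicates were numbered in deposition order within each group, and a number pairs no samples.

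Per the file headers, the authors deposited for each sample a whole-number read count per species-rank taxon, with the lineage of that taxon from domain to species. The deposited percent beside each count equalled the count divided by the sample's read total. The quality filters, the reference database and the classifier were not given in the sources used here. All 11 tables listed the same 292 species-rank taxa, in 174 genera, 84 families and 14 named bacterial phyla, with 1 group of bacteria in no phylum and 4 plant or algal rows. Names with a letter-number code (such as FJ881142_s, EF602759_g or EF602759_f for a species, genus or family) are the tables' placeholders for uncultured lineages, and "_uc" marks reads unclassified within the named rank. Such rows, 188 in number, held 38.4% of the listed reads.

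Read totals ranged from 1229 to 5378 in the lansoprazole group and from 3523 to 7506 in the control group. The deposited percentages summed to 100 within 0.01 in 10 samples. In lansoprazole replicate 4 they summed to 88.4, so 143 of the 1229 reads behind the percentages were in none of the listed rows. The total implied by the percentages served as library size, and the sum of listed reads was an alternative. All 25 pairs of samples within a group differed by more than sampling noise (highest chi-square p = 4.04e-58), so no library was repeated. A single-sample share carries a Wilson 95% interval where one is printed. A taxon with no read in a whole group was given a limit of 3 reads over that group's total, 0.0110% for controls. Fold changes against such a group were computed from the other group's mean share over this limit and are printed as lower bounds. The mean gives each rat equal weight, whereas the limit pools a group's reads. The bounds are therefore approximate, and higher than pooled reads would give where the reads lie in shallow libraries. Amplicon reads are not independent molecules, so intervals and limits cover counting error only.

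Read counts were summed to genus and phylum. Shannon index and the number of observed taxa were computed at species rank as means of 100 random draws of 1086 reads, the smallest listed total. Bray-Curtis distances of genus-level relative abundances were compared by PERMANOVA over every split of the samples into 6 and 5. Phylum shares and summed shares of taxon lists were compared by exact two-sided permutation tests of the difference in means, for which the smallest possible p is 0.00433, with Benjamini-Hochberg adjustment over the 5 phyla or 9 lists with a mean of at least 0.1% in either group. Counts per genus and species were tested with edgeR's quasi-likelihood test (robust fit), scaled by total count, for taxa with at least 10 reads in all and a read in at least 3 samples. This left 35 genera and 40 species. A taxon was called changed at a Benjamini-Hochberg adjusted p under 0.05. Each rat gave 1 sample per the labels' protocols, so the spread within a group includes differences between animals.

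Before the data were examined, 12 lists of taxa were fixed, together with the tests and most of the alternatives. The taxa named were also chosen by a fixed rule at genus and species rank. The rule takes up to 8 changed taxa per direction with the largest fold change and a mean of at least 0.1% in a group, the 10 most abundant taxa, and up to 4 genera of each tested list by mean share. Named outside this rule were Akkermansia, L. taiwanensis, Helicobacter pylori, Christensenellaceae_uc, HQ716403_g, Corynebacterium_uc, EF603943_g and Clostridium_g6. No name in the tables matched the fixed list of Bifidobacterium and Erysipelotrichaceae. Related taxa under other family names, EF603943_g of Allobaculum_f (4 lansoprazole reads) and Clostridium_g6 of Coprobacillus_f (1 control read), were not counted in it. The Akkermansia and plant lists were below 0.1% in both groups and were not tested.

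Alternatives were TMM scaling, DESeq2 with poscounts size factors, limma on centred log-ratios (pseudocount 0.5 reads), no count filter, edgeR's filterByExpr, a fit without the robust option, samples of 1 title letter only, and each sample left out in turn. Shares were also tested as ranks and as log2 of percent plus 0.01, and distances as Jaccard, Aitchison, square-root, species-rank and phylum-rank versions. Chosen after seeing the data were the library size from listed reads, removal of the skin, reagent and plant lists, removal of Clostridium_g4, a rank permutation test per taxon, and species-rank and phylum-rank versions of the title-letter comparison. The edgeR procedure was tested on simulated counts drawn from the means, dispersions and library sizes of the real samples. At genus rank it called 3.75% of genera changed by 3 log2 units, 23.8% of those changed by 6 log2 units and 0.741% of unchanged ones. At species rank it called 2.5%, 10.0% and 0.469% respectively. The simulated taxa were drawn independently of one another, whereas many real taxa had their reads in the same few rats. These rates therefore do not cover false calls that arise together, for which the splits of the real samples are given below. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.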

Results

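Luminal bacteria of the terminal ileum were compared between rats given the acid-suppressing drug lansoprazole in chow for 50 weeks and rats given plain chow. By their own labels, 6 samples belonged to the lansoprazole group and 5 to the control group, whereas the study's design text gives these numbers the other way round. Read totals were 3592 ± 1656 (SD, n = 6) in the lansoprazole group and 5449 ± 1673 (SD, n = 5) in controls, a difference that did not pass an exact permutation test (two-sided p = 0.113). The comparison asks whether long-term acid suppression goes with a different ileal microbiota.

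The ileum of control rats was dominated by Proteobacteria, the phylum of Escherichia and Pasteurella, and lansoprazole rats held more Firmicutes, the phylum of lactobacilli and clostridia. Firmicutes made up over 50% of reads in 4 of 6 lansoprazole samples, were close to Proteobacteria in replicate 1 (43.7% and 41.9%) and were below them in replicate 4 (33.4% and 47.0%). Firmicutes held 66.9% ± 28 of reads in the lansoprazole group (SD, n = 6) and 5.48% ± 4.38 in controls (SD, n = 5), 12.2-fold more on average. Proteobacteria fell from 93.9% ± 4.36 in controls (SD, n = 5) to 27.2% ± 22.0 in the lansoprazole group (SD, n = 6), 3.45-fold less. The groups did not overlap in either phylum. The lowest Firmicutes share under lansoprazole was 33.4% in replicate 4 (Wilson 95% interval 30.9 to 36.1), and the highest among controls was 10.6% in replicate 4 (9.61 to 11.6). Both differences passed the exact permutation test (p = 0.00433, the smallest it can give, and adjusted p = 0.0108 over 5 phyla).

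**Figure D1:**
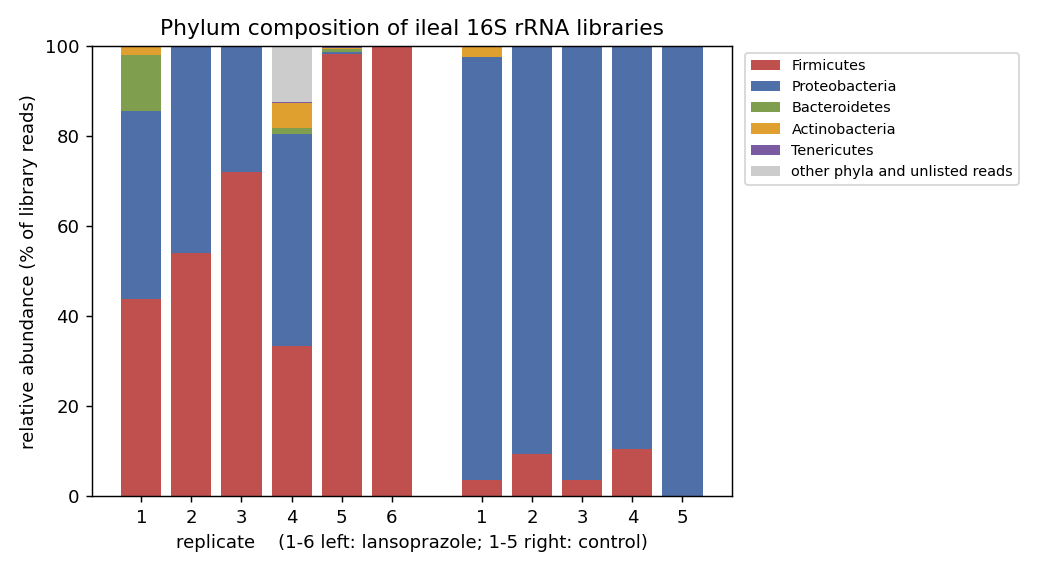
Stacked bars give the relative abundance of each phylum as a percent of library reads, 1 bar per rat, with 6 lansoprazole samples on the left and 5 controls on the right. Firmicutes lie between 33.4% and 99.7% under lansoprazole and reach at most 10.6% in controls.

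The other phyla did not pass the test. Bacteroidetes, anaerobes typical of the large intestine, had reads in 4 of 6 lansoprazole samples and in no control, at 2.40% ± 4.93 (SD, n = 6; exact permutation p = 0.0909, adjusted p = 0.152). Tenericutes had reads in 3 lansoprazole samples and no control, at 0.126% ± 0.151 (SD, n = 6; exact adjusted p = 0.303). Actinobacteria were at 1.29% ± 2.22 under lansoprazole (SD, n = 6) and 0.614% ± 1.03 in controls (SD, n = 5; exact adjusted p = 0.771), and without lansoprazole replicate 4 the mean difference turned to -0.185 percentage points. With samples of 1 title letter only, 3 against 5, the Firmicutes and Proteobacteria differences kept their directions, at an exact adjusted p of 0.0893 for each letter. The unadjusted p was the smallest that 3 against 5 samples can give, so the higher adjusted p does not show a weaker difference. With lansoprazole replicate 5 or 6 counted as a control, either of which gives the group sizes of the design text, the exact permutation p for Firmicutes was 0.0952 or 0.0996, and with any other lansoprazole sample so counted it was at most 0.0260. After removal of the genus Clostridium_g4, a step chosen after seeing the data, Firmicutes were higher by 37.7 percentage points in the lansoprazole group (exact adjusted p = 0.0866). Lansoprazole replicates 2 and 3 then lay within the range of controls.

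At genus rank the communities of the 2 groups differed as a whole. Treatment accounted for 30.3% of the variation in Bray-Curtis distance (exact permutation p = 0.00649, n = 6 and 5). Control samples were closer to one another, with a mean distance of 0.397, than lansoprazole samples, with 0.693, and the mean distance between groups was 0.746. The difference in within-group distance did not pass an exact permutation test (p = 0.0606), so the 2 groups may differ in spread as well as in location.

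A single taxon held most of the reads in all 5 controls and in 4 of 6 lansoprazole samples, the exceptions being lansoprazole replicates 1 and 4. The Escherichia coli group led in 4 of 5 controls, from 56.1% in replicate 2 (Wilson 95% interval 54.7 to 57.4) to 99.0% in replicate 5 (98.7 to 99.2). Pasteurella_g2_uc, unclassified members of a genus in the Pasteurellaceae, led in control replicate 4 with 64.5% (62.9 to 66.1). In the lansoprazole group FJ881142_s, an uncultured phylotype of Clostridium_g4, led in replicate 2 with 52.7% (51.1 to 54.2), in replicate 3 with 70.0% (68.8 to 71.2) and in replicate 6 with 99.1% (98.8 to 99.3). Lactobacillus johnsonii led in lansoprazole replicate 5 with 70.5% (68.5 to 72.5). The Escherichia coli group led in replicates 1 and 4, with 33.5% (32.0 to 35.1) and 23.9% (21.6 to 26.4).

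Of the 35 genera tested, 15 rose in the lansoprazole group and none fell by edgeR's quasi-likelihood test. Of 40 species-rank taxa, 12 rose and 1 fell. These counts rest on few animals. The genus count was 0 without control replicate 1, control replicate 4 or lansoprazole replicate 5, 1 without control replicate 2, 3 or 5, 2 without lansoprazole replicate 1 (Lactobacillus and Clostridium, both higher) and 4 without lansoprazole replicate 4 (3 of the 15, and Corynebacterium lower). It was also 0 when each genus was tested by an exact permutation of ranks (3 genera at unadjusted p under 0.05). The lowest adjusted p in that rank test was 0.152, reached at the smallest p the test can give. A single genus therefore cannot pass it over 35 genera, so the missing call decides nothing for Lactobacillus. The other called genera had no control read and reads in 3 or 4 lansoprazole rats. Their unadjusted p in the rank test was 0.0909 or 0.242, so they did not pass it before adjustment either. The 3 genera under 0.05 were Lactobacillus, Clostridium and Escherichia, of which edgeR called only Lactobacillus. DESeq2 called 2 genera and limma on centred log-ratios called 1. The species count was 0 without control replicate 1, 2 or 4, 1 without control replicate 3, and 3, 7 and 5 without lansoprazole replicates 1, 4 and 5.

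Lactobacilli, acid-tolerant fermenters of the upper gut, rose under most of the alternatives tried. Lactobacillus held 20.4% ± 32.8 of reads under lansoprazole (SD, n = 6) and 0.0378% ± 0.0460 in controls (SD, n = 5), with a log2 fold change of 8.96 ± 2.54 (SE; edgeR adjusted p = 0.0168). All 6 lansoprazole samples lay above all 5 controls, though narrowly, since the lowest lansoprazole share was 0.120% and the highest control share 0.118%. Replicates 5 (80.8%) and 1 (36.4%) carried the lansoprazole mean, and the median was 2.28%. At species rank, L. johnsonii rose to 12.7% ± 28.3 from 0.0206% ± 0.0461 in controls. L. intestinalis reached 2.75% ± 4.08 under lansoprazole, against 1 read in all controls. L. acidophilus, with no control read, was at 3.42% ± 7.54 and at least 310-fold higher, and L. reuteri was at 0.292% ± 0.507 and at least 26.5-fold higher (all SD, n = 6 and 5; edgeR adjusted p = 0.0244 each). Single rats supplied most of these means, with 70.5% L. johnsonii in lansoprazole replicate 5 and 18.8% L. acidophilus, 10.2% L. intestinalis and 1.26% L. reuteri in replicate 1. Without replicate 5 the log2 fold change of L. johnsonii went from 9.03 to 5.63 and its call was lost. Without replicate 1 that of L. acidophilus was 6.95 (at least 31.5-fold), that of L. reuteri 5.15 (at least 8.89-fold) and that of L. intestinalis 7.71, with the call of L. intestinalis lost. Lactococcus, a dairy and plant lactic acid bacterium, rose at least 28.3-fold to 0.311% ± 0.725 (SD, n = 6, edgeR adjusted p = 0.0264). Lansoprazole replicate 4, the shallowest library, supplied most of this mean with 1.79% (at least 1.40-fold without it). Enterococcus, at 0.0675% ± 0.0905 and 0.192% ± 0.291, did not pass the test (edgeR adjusted p = 0.586). In the fixed list of lactic acid bacteria 2 of 3 tested genera rose, with the same 2 when adjusted over the list alone. Lactococcus (24 lansoprazole reads), L. acidophilus and L. reuteri had no control read and could only rise, so their direction adds no support. The list's summed share of 20.7% ± 32.6 under lansoprazole (SD, n = 6) and 0.230% ± 0.287 in controls (SD, n = 5) did not pass (exact permutation p = 0.0736, adjusted p = 0.164 over 9 lists), and without replicate 5 the difference was 8.49 percentage points. The list leaves out Streptococcus (0.413% and 0.0998%, lansoprazole and control means) and Lactobacillales_uc_g (1.68% and 2.48%). With 1 sample left out the log2 fold change of Lactobacillus ran from 7.66 to 9.98, and adjusted p by edgeR from 0.00458 to 0.0752. The call was lost without control replicate 1, control replicate 4 or lansoprazole replicate 5, and with no count filter. In the rank test Lactobacillus had the smallest possible exact permutation p, 0.00433, and an adjusted p of 0.152 over 35 genera. A single genus cannot pass that test at these group sizes, so the missing call there decides nothing.

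Bacteria usual in the large intestine were found in lansoprazole rats and not in controls. The list of Lachnospiraceae and Ruminococcaceae, anaerobes that ferment plant fibre, had reads in 5 of 6 lansoprazole samples at a mean of 3.31% ± 4.36 (SD, n = 6), and 0 of 27244 control reads, which allows a share of up to 0.0110%. For the mean share over rats that is at least 301-fold higher, with an exact permutation p of 0.0260 (adjusted p = 0.117 over 9 lists). Lansoprazole replicates 2 and 3 had 1 such read each, on which this p rests, and without replicate 5 the difference was 1.78 percentage points. All 7 tested genera of this list rose by edgeR (adjusted p = 0.0264 each, and 7 when adjusted over the list alone). With no control read, a tested genus of this list could only rise, so their shared direction adds no support. Their reads came from 3 or 4 rats. That number alone fixed their exact permutation p in the rank test at 0.0909 or 0.242 (adjusted p = 0.369), so they could not pass it. The calls ended when any 1 control was left out, and 15 of 100 splits of the samples called as many genera as the real one. Among them Pseudoflavonifractor was at 0.851% ± 1.29 and at least 77.2-fold higher, GQ897654_g at 0.423% ± 0.833 and at least 38.4-fold, GU324404_g at 0.280% ± 0.409 and at least 25.4-fold, and Ruminococcaceae_uc at 0.237% ± 0.394 and at least 21.6-fold (all SD, n = 6). Without lansoprazole replicate 5 these bounds were 39.0-fold, 7.86-fold, 14.1-fold and 7.66-fold.

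Bacteroidales, the order of the large intestine's Bacteroidetes, had reads in 4 of 6 lansoprazole samples at 2.36% ± 4.93 (SD, n = 6) and in no control. This was at least 214-fold higher on average, but 12.4% in lansoprazole replicate 1 supplied most of it (difference 0.351 percentage points without it), and the exact permutation p was 0.0909 (adjusted p = 0.164). With no control read, a tested genus of this order could only rise. All 4 tested genera did so (edgeR adjusted p = 0.0264 each, and 4 when adjusted over the list alone). They were EU622749_g at 0.970% ± 2.15 and at least 88.1-fold higher, EF602759_f_uc at 0.656% ± 1.49 and at least 59.5-fold, EF602759_g at 0.271% ± 0.428 and at least 24.6-fold, and DQ815871_g at 0.164% ± 0.294 and at least 14.9-fold (all SD, n = 6). Without lansoprazole replicate 1 these bounds were 8.73-fold, 4.21-fold, 9.55-fold and 4.21-fold. The species HM124317_s of the same family, EF602759_f, rose at least 36.1-fold to 0.397% ± 0.859 (SD, n = 6; edgeR adjusted p = 0.0244), or at least 4.30-fold without replicate 1. The remaining 2 genera that rose, Christensenellaceae_uc and HQ716403_g, belong to the Christensenellaceae and were outside the naming rule. Reads of each called genus with no control read came from 3 or 4 lansoprazole rats, and these calls ended when any 1 control was left out.

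Clostridium_g4, a genus of the Peptostreptococcaceae, was the most abundant genus under lansoprazole but did not pass the test. It held 39.2% ± 41.1 of reads under lansoprazole (SD, n = 6) and 2.40% ± 3.53 in controls (SD, n = 5), with a log2 fold change of 4.03 ± 1.88 (SE; edgeR adjusted p = 0.0708). With 1 sample left out this fold change ran from 3.50 to 5.36. DESeq2 called this genus. Clostridium was at 0.478% ± 0.486 and 0.00883% ± 0.0198 (edgeR adjusted p = 0.0939), with reads in all 6 lansoprazole samples and 1 control. Turicibacter was at 0.0689% ± 0.0989 and 0.00389% ± 0.00871 (edgeR adjusted p = 0.124), and Peptostreptococcaceae_uc had 7 reads in 5 lansoprazole samples and none in controls. The list of Clostridiaceae, Peptostreptococcaceae and Turicibacter, common in the small intestine, was at 39.8% ± 41.0 under lansoprazole (SD, n = 6) and 2.41% ± 3.54 in controls (SD, n = 5; exact permutation p = 0.0390, adjusted p = 0.117). None of its 3 tested genera passed, also when adjusted over the list alone.

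Enterobacteriaceae, the family of Escherichia, were at 22.8% ± 19.5 under lansoprazole (SD, n = 6) and 72.7% ± 30.6 in controls (SD, n = 5), with an exact permutation p of 0.0173 and an adjusted p of 0.117 over 9 lists. None of its 5 tested genera passed, also when adjusted over the list alone. Escherichia was at 20.8% ± 17.4 and 71.5% ± 30.4 (log2 fold change -1.78 ± 1.52, SE; edgeR adjusted p = 0.351), and the Escherichia coli group at 17.2% ± 14.4 and 67.6% ± 31.6. E. fergusonii, whose 16S rRNA gene is close to that of E. coli so that the split between them is uncertain, was at 3.38% ± 2.83 and 3.49% ± 3.93. Enterobacter was at 1.68% ± 3.22 and 0.861% ± 1.48, of which E. cloacae made up 0.954% ± 2.05 and 0.0213% ± 0.0477. Citrobacter was at 0.155% ± 0.190 and 0.206% ± 0.344, and Klebsiella at 0.169% ± 0.404 and 0.0107% ± 0.0238. Lansoprazole replicate 2 supplied most of the lansoprazole means of Enterobacter (8.21%), E. cloacae (5.13%) and Klebsiella (0.994%). Without it the log2 fold change of Enterobacter turned to -1.20. Outside this family, Pasteurella_g2 was at 3.65% ± 5.97 under lansoprazole and 20.6% ± 26.4 in controls (all SD, n = 6 and 5; edgeR adjusted p = 0.269). Control replicate 4 alone held 64.5% of it, and the log2 fold change ran from -3.86 to -1.41 with 1 sample left out. Lactobacillales_uc_g, lactic acid bacteria not placed in a genus, were at 1.68% ± 3.84 and 2.48% ± 4.29.

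**Figure D2:**
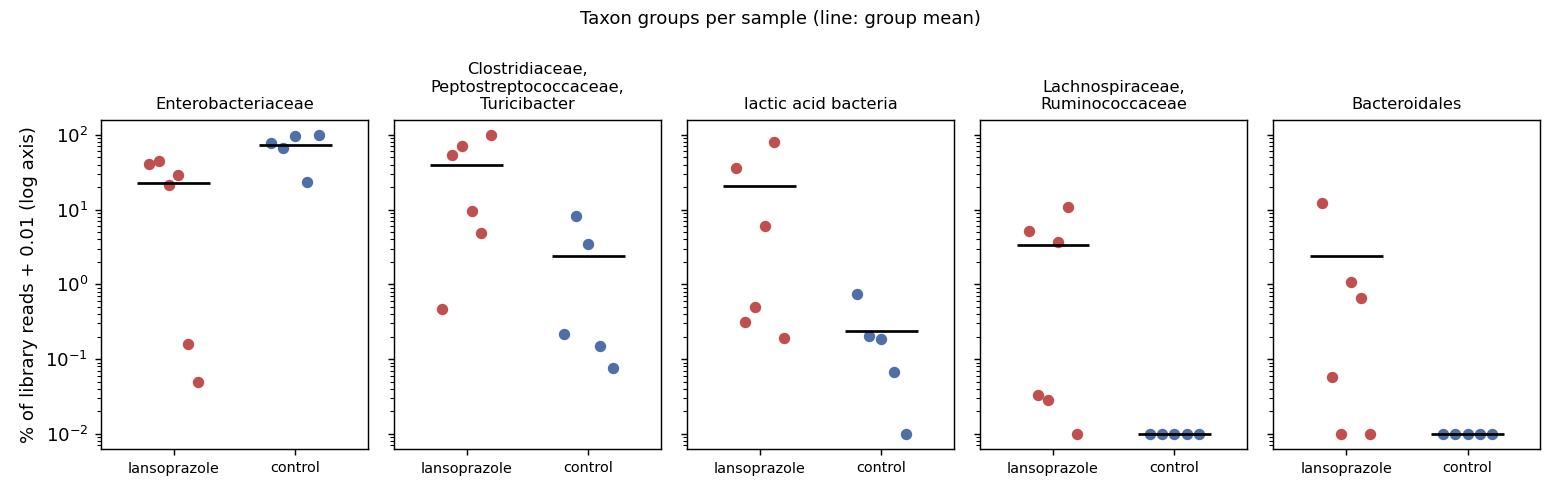
Points give each rat's summed share of reads for 5 taxon lists, as percent of library reads plus 0.01 on a log axis, and lines give group means (6 lansoprazole, 5 control). Lachnospiraceae and Ruminococcaceae had reads in 5 lansoprazole samples and in no control.

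Genera typical of the mouth, skin and laboratory reagents were measured as markers of other sources of bacteria. Oral-type genera were at 0.643% ± 1.28 under lansoprazole (SD, n = 6) and 0.122% ± 0.111 in controls (SD, n = 5; exact permutation p = 0.554, adjusted p = 0.623), and without lansoprazole replicate 4 the mean difference was -0.00107 percentage points. Streptococcus was at 0.413% ± 0.755 and 0.0998% ± 0.0993, and Veillonella at 0.112% ± 0.264 and 0.0172% ± 0.0108. Rothia had 5 reads under lansoprazole and 1 in controls, and Haemophilus 4 and 0. Skin-type genera were at 0.818% ± 1.35 and 0.675% ± 0.980 (SD, n = 6 and 5; exact permutation p = 0.840, the same after adjustment). Propionibacterium was at 0.686% ± 1.12 and 0.528% ± 0.928, nearly all P. acnes at 0.654% ± 1.08 and 0.491% ± 0.845. Staphylococcus was at 0.0869% ± 0.160 and 0.0761% ± 0.122, Corynebacterium had 1 read under lansoprazole and 16 in controls, and Micrococcus 3 and 0. The single species-rank taxon that fell, Corynebacterium_uc, lies outside the naming rule and had 0 reads under lansoprazole and 14 in controls (edgeR adjusted p = 0.0244). Reagent-type genera were at 0.184% ± 0.287 and 0.0272% ± 0.0507 (SD, n = 6 and 5; exact permutation p = 0.307, adjusted p = 0.395). Pseudomonas had 5 reads in each group, Sphingomonas 6 and 0, Methylobacterium 4 and 0, and Herbaspirillum 2 and 0. None of the 2, 3 and 1 genera tested in the oral, skin and reagent lists passed, also when adjusted over each list alone.

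The list of Helicobacter, Campylobacter, Desulfovibrionaceae and Mucispirillum, bacteria of the mucus layer, was at 0.184% ± 0.398 under lansoprazole (SD, n = 6) with no control read (exact permutation p = 0.242, adjusted p = 0.364). Its reads were mostly the 42 Helicobacter reads of lansoprazole replicate 2, and Mucispirillum and the Desulfovibrionaceae genus DQ815907_g had 1 read each. Akkermansia, a mucin degrader named because it had a list of its own, had 2 reads in 2 lansoprazole samples and none in controls. The list of plant plastids, mitochondria and Cyanobacteria had 8 reads under lansoprazole, 1 of them from Cyanobacteria, and 2 in controls.

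Diversity within samples did not differ between groups beyond the spread between rats. At 1086 reads, the Shannon index was 1.58 ± 1.02 under lansoprazole (SD, n = 6) and 0.800 ± 0.579 in controls (SD, n = 5; exact permutation p = 0.152). Observed species-rank taxa numbered 52.4 ± 45.5 and 15.6 ± 7.62 (SD, n = 6 and 5; exact permutation p = 0.0952). Without lansoprazole replicate 6, in which 1 phylotype held nearly all reads, the differences rose to 1.08 for the Shannon index and 45.6 for observed taxa, each at an exact permutation p of 0.0317. Without lansoprazole replicate 4, in which 130 taxa were observed, they fell to 0.506 and 21.2.

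**Figure D3:**
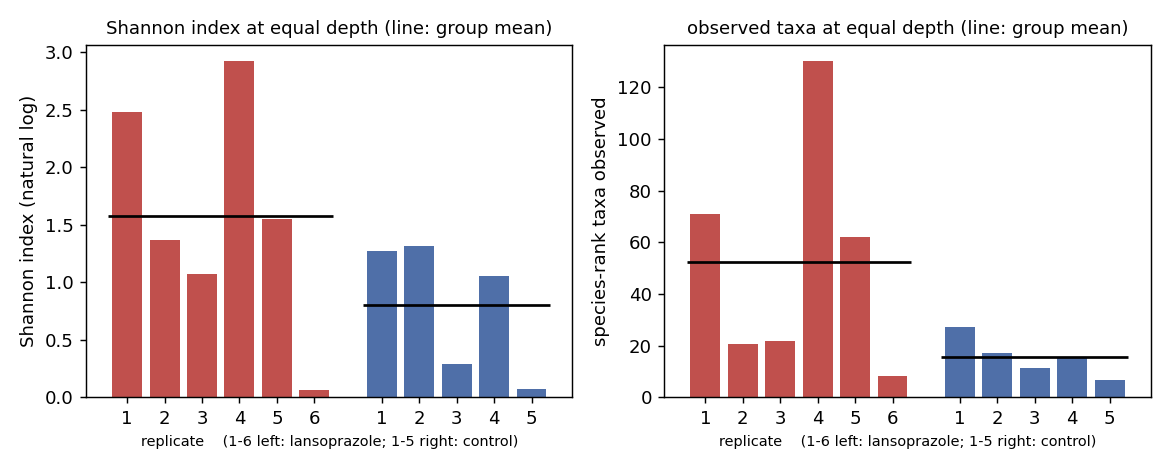
Bars give the Shannon index (natural log) and the number of species-rank taxa observed in each rat at 1086 reads, with lines at the group means. Lansoprazole samples span 8.32 to 130 observed taxa, and controls 6.84 to 27.2.

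Within the lansoprazole group, samples with B and H titles were compared because the letters may mark cages or batches. Title letter accounted for an R2 of 0.112 of the Bray-Curtis distances (exact permutation p = 0.700, n = 3 and 3). Firmicutes were at 56.6% ± 14.4 in B samples and 77.2% ± 37.9 in H samples (SD, n = 3 and 3; exact permutation p = 0.400). With 10 distinct splits the smallest p this comparison can give is 0.1. No title letter held samples of both groups, so letter and treatment could not be separated.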

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

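All tests of explanations in this part were chosen after the result they bear on had been seen. Of these, 2 were also changed after their own first outcome. The test of a mislabelled sample first joined moving 1 lansoprazole sample to the control group with leaving 1 sample out, and did not exclude the explanation. Limited to leaving samples out it appeared to exclude it, but that form was dropped, because with groups that do not overlap any such p is the smallest possible. A test of read depth, in which a control of 7506 reads had no read of the lower-gut groups and a lansoprazole sample of 3728 reads had them, was replaced by a test of reads outside Proteobacteria. The latter first compared mean shares, whose p was fixed by which samples had any read, and now gives no p but sets each lansoprazole sample against the control limit. A sample is listed here when it lies far from the other samples of its group by Dixon's ratio at the 95% level. Chance alone gives about 1 such sample in 20 groups, and 54 were found among 102 groups of values, many of them shares at or near 0 in most rats, for which the ratio is passed more easily.

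The first pattern is the higher Firmicutes and lower Proteobacteria share in lansoprazole samples. A single mislabelled sample stays open, since the stated group sizes conflict and counting 1 lansoprazole sample as a control gave exact p from 0.00433 (replicate 4) to 0.0952 (replicate 5) and 0.0996 (replicate 6), with differences of 39.6 and 39.1 percentage points for the last 2. No 1 sample supplied most of the difference, which was at least 54.8 percentage points with any 1 of the 11 left out. Reads of skin, reagent and plant taxa were too few to account for it, since none of these lists had a group mean above 0.818% of reads. Without them the difference was 61.8 percentage points (exact permutation p = 0.00433). So small a removal could hardly change it, so this p adds no further support. A cage or batch that goes with the title letter cannot be told apart from treatment, because no letter holds both groups, so both that and an effect of lansoprazole stay open (B against H gave an exact p of 0.400, but 3 against 3 samples give no p below 0.1, so this decides nothing).

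The second pattern is the presence of Lachnospiraceae, Ruminococcaceae and Bacteroidales reads in lansoprazole samples and their lack in controls. Control reads taken up by Proteobacteria could hide them. Among reads outside Proteobacteria, controls had 0 of 1404, a limit of 0.214%, and lansoprazole replicates 1, 4 and 5 had 30.3%, 8.91% and 11.7%. Control replicates 1 to 4 had none among 264, 487, 262 and 385 reads outside Proteobacteria. For lansoprazole replicates 1, 4 and 5 set against these controls, this argues against the explanation. Control replicate 5, with 6 reads outside Proteobacteria, decides nothing. Lansoprazole replicates 2 (0.131%), 3 (0.0258%) and 6 (0) lay below the limit too, so for them nothing can be decided. One shared source of contaminating DNA would carry these groups in 1 ratio, but Bacteroidales made up 70.4%, 22.4% and 5.60% of them in lansoprazole replicates 1, 4 and 5 (chi-square p = 6.47e-68). Contents of each rat's own lower gut in the ileal flush remain possible for the 3 samples with at least 20 such reads, and no lower-gut sample was analysed here. An effect of lansoprazole or of a shared cage stays open as well.

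The third pattern is the fraction of Escherichia reads assigned to E. fergusonii among those assigned to it or the E. coli group. In the 4 lansoprazole samples with at least 100 Escherichia reads it was 16.5% ± 0.473 (SD, n = 4), and in controls 6.09% ± 5.97 (SD, n = 5), from 0.295% to 14.9% (exact permutation p = 0.0159). A fixed rate of misassigned E. coli reads would give 1 fraction everywhere, which the spread excludes (chi-square 2034 on 8 degrees of freedom over 9 samples), though reads are not independent molecules. A fall of the fraction as Escherichia takes more of the library cannot be told apart from treatment, with Spearman's rho of -0.767 (permutation p = 0.0214) and Pearson's r of -0.794 (permutation p = 0.0208), which moved to -0.371 without the 2 samples farthest from the median share, although the 1 control of similar share, replicate 4 (share 23.3%), had a fraction of 7.87% (Wilson 95% interval 6.21 to 9.93), below lansoprazole replicates 3 (share 20.2%, fraction 17%, 14.9 to 19.4) and 4 (share 28.6%, fraction 16.0%, 12.5 to 20.2), and 1 library excludes nothing. A different Escherichia population in lansoprazole rats is a candidate explanation, since their fractions differed by no more than sampling noise (chi-square p = 0.930). However, control replicate 2, at 14.9% (Wilson 95% interval 13.8 to 16.2), overlapped the intervals of all 4 lansoprazole samples. A cage or batch that goes with the title letter cannot be told apart from treatment here either.

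The counts of changed taxa were set against 100 splits of the 11 samples into 6 and 5, the real one included. For genera, 15 of the 100 splits called as many as the real 15, with up to 17 in another split, so chance cannot be excluded. For species, 2 of the 100 splits called as many as the real 13, with at most 13 in another split. This share, the real split included, is under 0.05, but its 95% interval of 0.550% to 7% reaches past that. The interval treats the real split as drawn at random, although it was always included, so it is approximate. Chance is therefore not firmly excluded.

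Lansoprazole replicate 4, the shallowest library, stood apart in Actinobacteria (5.61% of reads), oral-type genera (3.25%) and reagent-type genera (0.732%). Among single genera it did so in Lactobacillales_uc_g (9.52%), Streptococcus (1.95%), Lactococcus (1.79%), Veillonella (0.651%), Staphylococcus (0.407%) and Haemophilus (0.325%). Enterococcus, Rothia and Methylobacterium were at 0.244% each, Micrococcus and Herbaspirillum at 0.163% each, and Corynebacterium and DQ815907_g at 0.0814% each. In this library of 1229 reads, 0.244% is 3 reads and 0.0814% is 1 read, so these values are at or near the floor.

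Lansoprazole replicate 1 stood apart in Bacteroidetes (12.4%) and in the Bacteroidales list (12.4%), with EU622749_g at 5.34%, EF602759_f_uc at 3.70%, HM124317_s at 2.15%, EF602759_g at 1.10% and DQ815871_g at 0.751%. It also did so in Lactobacillus acidophilus (18.8%), L. reuteri (1.26%) and Mucispirillum (0.0268%, 1 read). Lansoprazole replicate 2 stood apart in Enterobacter (8.21%), E. cloacae (5.13%), Klebsiella (0.994%), Helicobacter (0.994%) and the mucus-layer list (0.994%). Lansoprazole replicate 5 did so in L. johnsonii (70.5%), GQ897654_g (2.10%) and Ruminococcaceae_uc (1.00%).

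Control replicate 1 stood apart in Actinobacteria (2.45%), the lists of skin-type genera (2.40%), lactic acid bacteria (0.723%) and reagent-type genera (0.117%), and in Enterobacter (3.50%), Propionibacterium (2.17%), P. acnes (1.98%), Citrobacter (0.816%), Enterococcus (0.700%), Pseudomonas (0.117%) and Rothia (0.0233%). The Rothia value rested on 1 read. Control replicate 2 stood apart in Staphylococcus (0.292%) and Turicibacter (0.0195%, 1 read). Control replicate 3 did so in Lactobacillus (0.118%), L. johnsonii (0.103%), Clostridium (0.0442%) and L. intestinalis (0.0147%, 1 read). Control replicate 4 did so in Lactobacillales_uc_g (9.93%), and control replicate 5 in E. cloacae (0.107%) and Klebsiella (0.0533%).

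Outside the bacterial comparisons, plant reads reached 0.244% of the library in lansoprazole replicate 4, against at most 0.0467% in a control. The same sample had 143 reads behind its percentages that were in none of its listed rows, and no other sample had any such reads.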

How the results depend on the processing

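Alternatives chosen after seeing the data are the library size from listed reads, the removal of skin, reagent and plant taxa or of Clostridium_g4, the rank test per taxon and the ranks used for the title-letter comparison. The group difference in Bray-Curtis distance passed under every alternative run, with R2 from 0.271 to 0.364 when 1 sample was left out, 0.180 for Jaccard distance and 0.746 at phylum rank. The Firmicutes difference ran from 54.8 to 68.1 percentage points and the Proteobacteria difference from -70.7 to -61.3 without 1 sample. All of these differences passed the threshold, which groups that do not overlap guarantee. With B or H titles only these were 51.1 and 71.7 points for Firmicutes and -55.4 and -78.0 for Proteobacteria, each at the smallest exact p that 3 against 5 samples give and at an adjusted p of 0.0893. Without Clostridium_g4 they were 37.7 and -45.8. This genus held 52.8% and 70.3% of reads in lansoprazole replicates 2 and 3, out of 54.0% and 72.1% for all Firmicutes. Without it these samples lay within the range of controls, so the groups overlapped and the call was lost. Lansoprazole replicate 6, with 99.2% Clostridium_g4, was left with few reads. No paired analysis was possible because the replicate numbers only name samples. The planned pseudocount for share-only files did not apply, since the files hold counts.

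The genus count of 15 became 2 with DESeq2, 1 with limma, filterByExpr, B titles only or H titles only, 0 with no filter (edgeR, 49 at unadjusted p under 0.05) or the rank test (3 at unadjusted p under 0.05), and 0 to 15 with 1 sample left out. The species count of 13 became 6 with DESeq2, 4 with B titles only, 1 with filterByExpr or H titles only, 0 with limma (9 at unadjusted p under 0.05), no filter (62) or the rank test (3), and 0 to 15 with 1 sample left out. Fewer taxa were tested under filterByExpr and in subsets, and more with no filter. In the rank test the lowest adjusted p was 0.152 for genera and 0.173 for species. No single taxon can pass that test at these group sizes, so a missing call there decides nothing for Lactobacillus or L. johnsonii. The other called taxa had an unadjusted p of at least 0.0909 in the rank test, so they did not pass it before adjustment either. The cause of the other changes was not tested. Left-out samples moved the Shannon difference between 0.506 and 1.08 and that in observed taxa between 21.2 and 45.6, both past the threshold without lansoprazole replicate 6 only.

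Differences that never passed turned direction as follows, and the cause was not tested. Actinobacteria were at -0.183 mean ranks, at -0.0201 points with B titles, and at -0.185 to 1.14 with 1 sample left out. Oral-type genera were at -0.0108 with B titles and -0.00107 to 0.640 with 1 sample left out. Skin-type genera were at -1.47 mean ranks, -1.11 on the log2 scale, -0.185 with B titles and -0.361 to 0.574 with 1 sample left out. Log2 fold changes with limma were -1.22 for Enterobacter, -1.13 for Propionibacterium, -1.07 for P. acnes, -0.76 for Veillonella, -1.03 for Staphylococcus and -0.34 for Pseudomonas. With B titles they were -0.21 for Propionibacterium, -0.22 for P. acnes, -0.0851 for Streptococcus, -1.47 for Staphylococcus, 0.45 for Citrobacter and 0.58 for E. fergusonii. With H titles they were 0.40 for Lactobacillales_uc_g and its 1 species-rank taxon and -2.23 for Enterobacter. E. fergusonii was at 0.15 with TMM and 0.22 with DESeq2, and Citrobacter at 0.22 with DESeq2. With 1 sample left out, the ranges were -4.51 to 1.45 for Lactobacillales_uc_g and its species-rank taxon, -1.20 to 3.04 for Enterobacter, -0.88 to 2.51 for Propionibacterium, -0.88 to 2.44 for P. acnes, -0.36 to 0.83 for E. fergusonii, -1.54 to 1.79 for Staphylococcus and -1.20 to 1.49 for Citrobacter.

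Among named taxa, 572 alternative values kept direction and side of the threshold, 138 lost a call at the same direction, 6 gained one and 33 turned direction.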

Other observations

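Helicobacter was found in 1 rat. Its 42 reads, 0.994% of the library of lansoprazole replicate 2, were all assigned to Helicobacter pylori in the deposited tables, and the other 10 samples had none. The same rat carried the highest share of Enterobacter in the study, 8.21%, with E. cloacae at 5.13%, and of Klebsiella, 0.994%.

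The lactobacilli of lansoprazole rats differed in makeup from rat to rat. Replicate 5 held mostly L. johnsonii (70.5% of reads) with 4.76% L. intestinalis, 3.51% L. taiwanensis and 0.902% L. acidophilus. Replicate 1 held 18.8% L. acidophilus, 10.2% L. intestinalis and 4.64% L. johnsonii. Lansoprazole rats rich in Clostridium_g4 had little Lactobacillus and the reverse. Clostridium_g4 was at 0.322% and 3.31% in lansoprazole replicates 1 and 5, where Lactobacillus was at 36.4% and 80.8%, and at 52.8%, 70.3% and 99.2% in replicates 2, 3 and 6, where Lactobacillus was at 0.260%, 0.483% and 0.120%. In replicate 4 the 2 genera were at 9.36% and 4.07%. No test of this was run, and shares of 1 total move against each other by construction.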
